A study of Mus musculus with 8 samples.

How the data were processed

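RNA-seq libraries from CD4+ T cells of the spleen of wild-type C57BL/6 mice were analysed, 8 libraries in 4 groups of 2. The groups were naive cells taken directly from the spleen, Th0 cells stimulated through CD3 and CD28 for 3 days, and cells kept for 3 days under Th17 or under Treg differentiation conditions. Group and replicate number came from the sample titles. The replicate numbers were 1 and 2 for naive, 1 and 3 for Th0, and 2 and 3 for Th17 and Treg. No label said that the libraries of a group came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical.

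Per the labels' protocols, total RNA was extracted with TRIzol and sequenced at the Beijing Genomics Institute on an Illumina HiSeq instrument. The submitters' processing notes name Bowtie2, RSEM and the builds GRCm38.p6 and mm10, without versions of the tools. The role of each tool, the annotation release and the strandedness of the libraries were not given in the sources used here. One table held, per the file headers, a count and an FPKM value for each of 34745 Ensembl genes in each library. The deposited counts were whole numbers, and whether they are rounded RSEM estimates is not stated. The deposited FPKM values equalled the count divided by the library total and by 1 fixed length per gene, within a relative tolerance of 0.001, for 100.0% of the 134607 values above 0. They held nothing beyond the counts and were not used further. Of the rows, 34267 matched a gene of the GENCODE annotation of GRCm38 by identifier, and 80.8% of those had identical coordinates, so coordinates are given on GRCm38. Symbols are those of the table, which uses some older names such as Whsc1l1 for Nsd3 and Ppap2b for Plpp3.

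Total counts were 20225716 and 22443368 in the naive libraries, 16332971 and 13976564 in Th0, 16584279 and 13344484 in Th17, and 14767329 and 12504463 in Treg. A count of 0 in 1 library allowed a level of up to 0.134 to 0.24 CPM (counts scaled to a common library total), taking 3 counts as the limit, and this covers counting error only. For folds against a group with no count in either library, the limit of 3 counts per library was converted with the TMM-scaled library sizes and averaged over the group, and the fold is given as a lower bound. Without strand information in the sources, reads of overlapping antisense genes cannot be separated, and near-identical genes such as Hspa1a and Hspa1b or the Gbp and globin families may share reads, so values of single members are uncertain. Genes annotated as pseudogenes took 1.79% to 2.42% of the counts of a library.

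Counts were tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1), with all 8 libraries in 1 fit of group means. Genes were kept with filterByExpr by group, which left 14690 genes, and library sizes were scaled with TMM factors. Dispersions were estimated with estimateDisp (common biological coefficient of variation 0.13), and contrasts were tested with glmQLFit and glmQLFTest on 4 residual degrees of freedom (median prior degrees of freedom 5.22). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 per contrast. Standard errors (SE) are the log2 fold change divided by the square root of the F statistic. The contrasts were Th0 against naive, Th17 against Th0, Treg against Th0 and Th17 against Treg, with Th17 and Treg against naive added for Setd2. Levels are TMM-scaled CPM, as mean ± SD.

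Before the data were examined, 28 gene lists with 552 entries were fixed, together with the design, the alternatives to the test and the rule for the genes named in the text. The rule took, per contrast, the 6 called genes with the highest and the 6 with the lowest log2 fold change that reached a mean of 10 CPM in the higher group with both of its libraries above both of the other group. It left out predicted genes, pseudogenes and antigen receptor segments. The rule also took 8 fixed genes per contrast, up to 4 members of each list described (the called ones with the greatest change) and Setd2. Genes named outside the rule were chosen after their values were seen. Some genes picked by the rule are not reported here. The added genes are other members of the fixed lists, given for their levels or as markers of other cell types, and genes of the lists added later. All but 1 of the entries matched a row of the table, 12 of them through the reference tables.

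Lists were tested with camera (limma) at a preset inter-gene correlation of 0.01, adjusted over 28 lists and 4 contrasts. Camera compares the genes of a list with all other genes. The test was repeated with the correlation estimated per list, and with fry, which asks whether a list's genes move one way on balance. Fixed beforehand were also RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter at 5 CPM in 2 libraries, fits of only the 2 groups compared, a test against a 2-fold change, the replicate number as a block, and leaving out each library in turn, where the lone library of a group is assumed to vary like the other groups. Fits without the 2 naive libraries and without marker genes of other cell types were added after seeing the data.

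The test was checked on simulated counts drawn from the means, library sizes and dispersions of these libraries, with 100 genes changed 2-fold and 100 changed 4-fold per contrast. For Th0 against naive (14336 genes), 67% of the 2-fold and 85% of the 4-fold changes were called, and 9% of the calls were false. The values were 63%, 80% and 9.5% for Th17 against Th0 (14440 genes), 55%, 83% and 5.5% for Treg against Th0 (14476 genes), and 69%, 83% and 10.1% for Th17 against Treg (14452 genes). The share of false calls thus lay above the nominal 5% in each of these 4 simulations. Far fewer genes were changed in them than were called in the data (28.7% to 67.7% of the tested genes), so both shares hold for that setting only. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.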

Results

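The libraries profile mouse splenic CD4+ T cells in 4 states, with 2 libraries each: naive cells, Th0 cells activated through the T cell receptor and CD28, and cells cultured under Th17 conditions (a helper state that makes IL-17) or Treg conditions (a suppressive state defined by Foxp3). All mice were wild type. The series title concerns the histone methyltransferase Setd2 and phospholipid remodeling, so these libraries can address how Setd2 and related gene groups differ between the states. Total counts per library ran from 12504463 to 22443368. Replicates correlated at 0.9878 to 0.9918 (Pearson r of log2 CPM across genes, which are not independent), and they differed by more than counting noise in each group (chi-square per degree of freedom 9.32 to 18.59). The first principal component (68.9% of the variance) separated naive from cultured libraries, and the next components (14.4% and 9.1%) separated Th0, Th17 and Treg.

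Setd2 was lower in both differentiated states than in naive or Th0 cells. Setd2, which places trimethyl marks on lysine 36 of histone H3, lies on chromosome 9 from 110532597 to 110618633 (ENSMUSG00000044791). It measured 276 ± 14.8 CPM in naive cells, 276 ± 28 in Th0, 198 ± 24.2 in Th17 and 168 ± 0.611 in Treg (SD, n = 2). Its log2 fold change was -0.71 (SE 0.11, edgeR adjusted p = 0.00085) in Treg against Th0, 61.0% of the Th0 level, and -0.48 (SE 0.11, edgeR adjusted p = 0.0111) in Th17 against Th0, 71.8% of the Th0 level. Both libraries of each differentiated state lay below both Th0 libraries. Against naive cells the changes were also -0.71 and -0.48 (edgeR adjusted p = 0.000454 and 0.00398). Th0 and naive cells differed by a log2 fold change of 0 (SE 0.11, edgeR adjusted p = 0.996), and Th17 and Treg by 0.23 (SE 0.11, edgeR adjusted p = 0.14). Adjusted over the 6 contrasts of this gene alone, the edgeR p was 0.0003 for Treg against Th0 and 0.00251 for Th17 against Th0. The Th17 against Th0 call was lost without Th0 replicate 3 (-0.38, edgeR adjusted p = 0.0684) or Th17 replicate 2 (-0.36, 0.0625), and the Th17 against Treg difference passed without Th17 replicate 2 (0.35, 0.0456). None of these changes passed a test against a 2-fold change. The share of T cells in each library was not measured, and markers of other cell types differed between the groups. Of 18 pan T cell genes, 9 were lower and 1 higher in Th17 against Th0 (median log2 fold change -0.3). In Treg against Th0, 7 were lower and 5 higher (median -0.11). Whether Setd2 changed, or stayed level between naive and Th0, within T cells was therefore not tested.

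**Figure D1:**
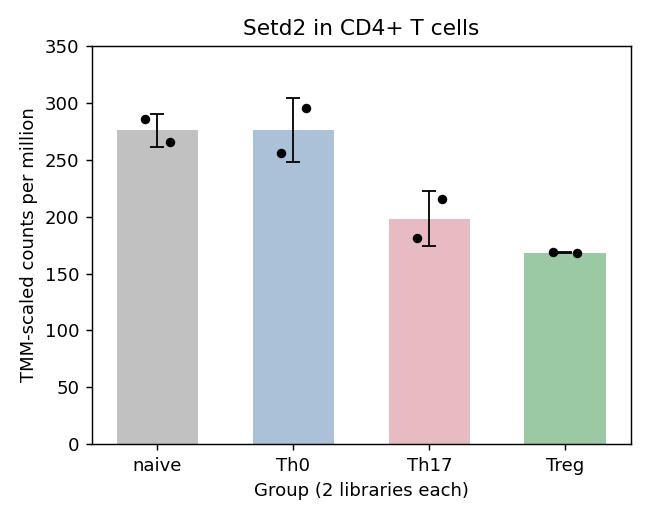
Setd2 in TMM-scaled CPM (vertical axis, from 0) in the 4 groups. Bars are means of 2 libraries, error bars are SD and points are libraries; the Treg libraries lie at 168 and 169 and the Th0 libraries at 256 and 296.

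Genes around histone H3 lysine 36 methylation changed in a mixed way. Of the 22 tested genes in the list of enzymes and readers of this mark, 11 rose and 5 fell in Th0 against naive. The related methyltransferase genes Whsc1 (log2 fold change 2.49, SE 0.12) and Whsc1l1 (1.14, SE 0.12) rose, as did the mismatch repair gene Msh6 (1.41, SE 0.09), whose product binds the mark. In Treg against Th0, 3 rose and 7 fell, including Whsc1l1 (-1.01, SE 0.12, edgeR adjusted p = 0.000198) and Morf4l1 (-0.75, SE 0.1), while Smyd2 rose (1.29, SE 0.2). In Th17 against Th0, 2 rose and 4 fell, among them Setd2 and the demethylase gene Kdm2b (-0.51, SE 0.09). In Th17 against Treg, 4 rose and none fell. Adjusted over the list alone, the falls were 6, 7, 5 and 0 and the rises were 11, 3, 2 and 4, in the order Th0 against naive, Treg against Th0, Th17 against Th0 and Th17 against Treg. As a group the list did not pass camera in any of these contrasts (adjusted p = 0.146, 0.133, 0.33 and 0.41), though it passed in Treg against Th0 with no filter on low counts (0.0464). Among 25 other histone lysine methyltransferases, Ezh2 rose in Th0 against naive (2.26, SE 0.11) and fell in Th17 against Th0 (-0.64, SE 0.11). That list did not pass either (camera adjusted p = 0.408 to 0.982).

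After 3 days of stimulation, cell cycle and sterol genes were higher in Th0 than in naive cells and genes of resting cells were lower. The naive libraries were not cultured and held more transcripts of other cell types, with summed B cell markers at 4010 and 3310 CPM against 607 and 624 in Th0. Changes in this contrast, falls above all, can therefore not be credited to stimulation alone. Of 26 proliferation genes, 25 rose and none fell, with Top2a, a topoisomerase of dividing cells, going from 174 to 2370 CPM (log2 fold change 3.76, SE 0.11) and Mki67 from 261 ± 0.736 to 1970 ± 184 CPM (2.92, SE 0.11, edgeR adjusted p = 6.19e-08). Of 22 cholesterol synthesis genes, 20 rose and none fell, led by Fdps (2.84, SE 0.14) and Msmo1 (2.63, SE 0.16). The desaturase gene Scd2 rose from 133 to 1770 CPM (3.73, SE 0.12), within a fatty acid synthesis list in which 12 of 20 rose and 4 fell. Of 20 serine, one-carbon and ATF4 genes, 14 rose and 2 fell, with asparagine synthetase Asns going from 3.85 to 130 CPM (5.08, SE 0.17). Of 19 glycolysis genes, 12 rose, including Aldoa (2.35, SE 0.09), and 3 fell, including Hk2 (-1.4, SE 0.19). These lists passed camera (adjusted p = 6.88e-23 for proliferation, 1.32e-08 for cholesterol, 0.002 for fatty acid synthesis, 6.32e-05 for serine and ATF4, and 3.85e-05 for glycolysis). None passed with an estimated correlation (adjusted p = 0.107, 0.322, 0.448, 0.259 and 0.299 with an estimated correlation). Adjusted over the list alone, all 26 proliferation genes rose and the other counts were the same.

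Of 22 T cell activation genes, 10 rose and 9 fell in Th0 against naive (11 and 9 adjusted over the list alone; camera adjusted p = 0.178). The activation receptors Lag3 (log2 fold change 3.29, SE 0.11), Tnfrsf9 (2.83, SE 0.15) and Tnfrsf4 (2.61, SE 0.14) rose, as did the IL-2 receptor chain Il2ra, from 83.6 ± 0.834 to 315 ± 11.8 CPM (1.92, SE 0.12, edgeR adjusted p = 1.23e-06). The cytotoxic protease gene Gzmb rose from 11.6 to 335 CPM (4.85, SE 0.15). Among naive and quiescence genes, 13 of 22 fell and 3 rose (camera adjusted p = 0.01, and 0.339 with an estimated correlation; the same counts adjusted over the list alone). Klf2, a regulator of T cell trafficking, fell from 475 ± 4.07 to 22.9 ± 2.79 CPM (-4.37, SE 0.16), and Klf3 fell too (-3.24, SE 0.11). Tcf7 rose (0.7, SE 0.12, edgeR adjusted p = 0.000505). Cd44, usually raised on activated T cells, was lower in Th0 (104 ± 6.78 against 251 ± 23.9 CPM; -1.27, SE 0.11, edgeR adjusted p = 6.03e-06). Small falls of Il7r (-0.28, SE 0.09) and Myc (-0.5, SE 0.17) each lost their call when single libraries were left out. For Il7r these were naive replicate 2 (-0.17, edgeR adjusted p = 0.205) or Th0 replicate 1 (-0.21, edgeR adjusted p = 0.133). For Myc they were naive replicate 1 (-0.49), naive replicate 2 (-0.53) or Th0 replicate 3 (-0.38), with edgeR adjusted p = 0.0852, 0.0695 and 0.158.

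Markers of other spleen cells moved with this contrast. All 19 myeloid and dendritic cell markers fell in Th0 against naive, and so did all 12 B cell, 7 NK cell and 7 red blood cell markers that were tested, with the same counts adjusted over the list alone. Csf1r, the receptor for macrophage growth factor, lay at 862 and 820 CPM in the naive libraries and at 0.33 and 0.154 in Th0, and Mpeg1 lay at 963 and 934 against 6.34 and 5.47. The complement gene C1qb (273 ± 20.9 CPM in naive), the receptor Adgre4, the neutrophil granule gene Ngp, the prostaglandin dehydrogenase Hpgd, the matrix gene Tgfbi and the phagocytic receptor Mertk had no count in either Th0 library, so they were at least 1280, 901, 614, 605, 599 and 550-fold lower. The myeloid and red blood cell lists also passed with an estimated correlation (camera adjusted p = 0.0186 and 0.0496), and the B and NK cell lists did not (adjusted p = 0.201 for each with an estimated correlation). The 2 tested CD8 T cell markers rose, Cd8a from 48.3 to 112 CPM (1.21, SE 0.14) and Cd8b1 (0.73, SE 0.1). In the same contrast 15 of 22 interferon-stimulated genes fell and none rose, such as Ifit3 (41.0 to 0.677 CPM) and Oasl2 (41.7 to 0.215 CPM; camera adjusted p = 8.86e-06, and 0.248 with an estimated correlation). Among stress and dissociation genes, 10 of 15 fell and 5 rose (camera adjusted p = 4.15e-07, and 0.201 with an estimated correlation). Counts of both lists were the same adjusted over the list alone. The immediate early genes Fos (-6.39, SE 0.2) and Dusp1 (-6.23, SE 0.13) were among those that fell, and Hspa1b rose (5.94, SE 0.7) from 6.84 and 1.95 CPM in the naive libraries, which lie far apart. Foxp3 was at 98.2 CPM in naive cells and 5.32 in Th0 (-4.2, SE 0.22).

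**Figure D2:**
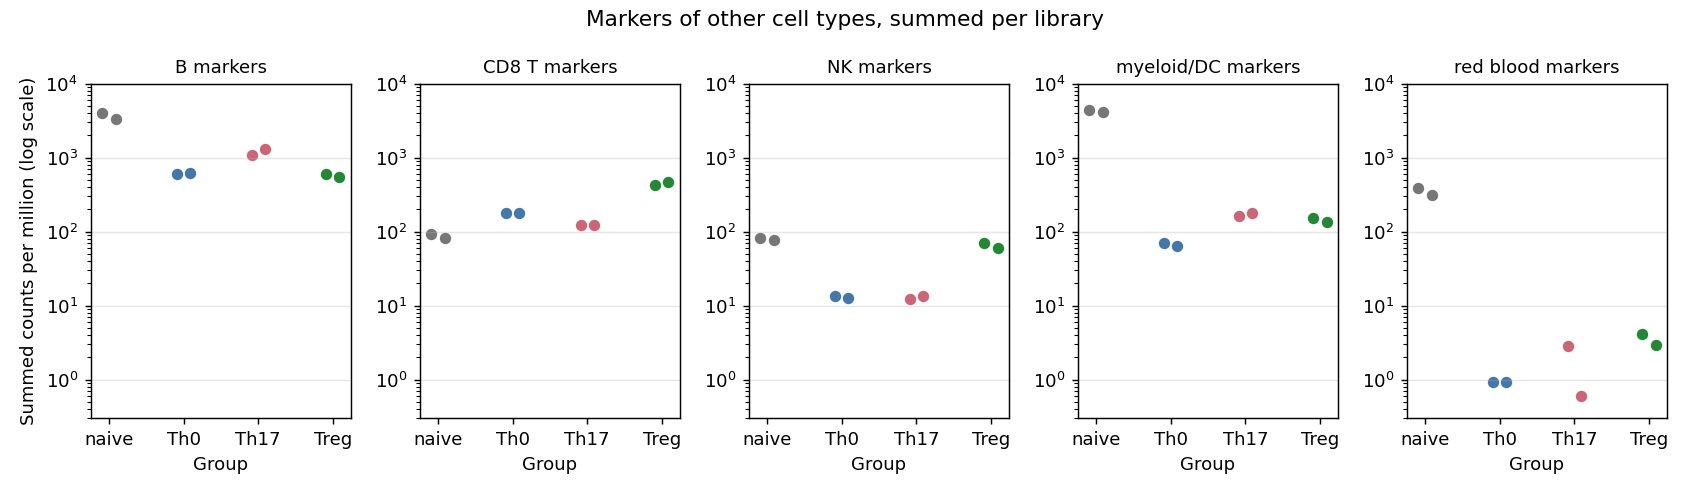
Summed TMM-scaled CPM (log scale) of the tested markers of B cells, CD8 T cells, NK cells, myeloid and dendritic cells (DC), and red blood cells, 1 point per library. The naive libraries sum to 4390 and 4150 for myeloid markers against 70.2 and 63.4 in Th0.

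Other genes with the greatest rises in Th0 were Serpinb5, a serpin family gene (43.2 ± 0.92 CPM, no count in naive, at least 315-fold higher), thyroglobulin Tg (1.41 to 307 CPM; log2 fold change 7.76, SE 0.22), Cth (6.87, SE 0.39), Lonrf3 (6.84, SE 0.35), Tnip3 (6.78, SE 0.25) and Ybx2 (3 counts in total in naive, 16.8 ± 1.65 CPM in Th0). Over all 14690 genes, 4600 rose and 5342 fell in Th0 against naive, of which 2368 and 3511 changed at least 2-fold. The count was 4231 when tested against a 2-fold change, and 9867 after removal of marker genes of other cell types, a fit chosen after seeing the data. That removal left 14630 genes in the test and all other transcripts of such cells in place. It therefore cannot show how many calls come from other cells.

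Th17 conditions raised the Th17 program over activation alone. Of 20 tested Th17 genes, 17 rose and none fell against Th0, also when adjusted over the list alone (camera adjusted p = 4.69e-27, and 0.0377 with an estimated correlation). Il17f rose from 0.875 ± 0.396 to 112 ± 32.6 CPM (log2 fold change 7.03, SE 0.41, edgeR adjusted p = 1.26e-05) and Il17a from 1.31 ± 0.00818 to 47.3 ± 19.2 CPM (5.16, SE 0.45, edgeR adjusted p = 7.75e-05). The 2 cytokine genes are neighbours on chromosome 1 (20777146 to 20790617 and 20730905 to 20734496). Il22 rose (6.65, SE 0.58), and Rora rose (1.19, SE 0.13). Il23r rose from 0.567 to 3.53 CPM (2.63, SE 0.54), a call lost without Th17 replicate 2 (1.89, edgeR adjusted p = 0.0723).

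Genes of the signals that accompany this state moved as well. Of 20 TGF-beta response genes, 11 rose and 1 fell, including Skil (log2 fold change 1.59, SE 0.23). Of 14 genes of the IL-6 and STAT3 response, 9 rose and 1 fell, including Il21 (13 to 62.9 CPM; 2.27, SE 0.24) and Il6ra (1.58, SE 0.1). Glycolysis genes rose in 12 of 19 cases and 1 fell, with hexokinase Hk2 going from 13 to 123 CPM (3.25, SE 0.19). Hypoxia response genes rose in 11 of 20 cases and 1 fell, with Egln3 at 2.19 (SE 0.2). Of 22 Treg genes, 12 rose and 4 fell, including Ikzf4 (1.96, SE 0.15) and Gpr15 (2.61, SE 0.26). Foxp3 itself measured 7.92 ± 2.84 against 5.32 ± 0.881 CPM (0.59, SE 0.24, edgeR adjusted p = 0.0947), and passed without Th17 replicate 3 (0.9, edgeR adjusted p = 0.00927), with no filter on low counts (0.57, 0.00628) and with DESeq2 (0.55, DESeq2 adjusted p = 0.0481). These 5 lists passed camera (adjusted p = 0.000552, 0.000507, 3.95e-05, 0.00089 and 0.00171) but not with an estimated correlation (adjusted p = 0.117, 0.112, 0.319, 0.285 and 0.201 with an estimated correlation). Adjusted over the list alone, rises and falls were 12 and 1, 9 and 2, 12 and 3, 11 and 1, and 14 and 4.

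Gzmb, Tbx21 and other genes of the Th1 list were lower in Th17 than in Th0, while some members rose. Both tested CD8 T cell markers fell as well, Cd8a from 112 to 76.8 CPM (log2 fold change -0.55, SE 0.14) and Cd8b1 from 63.9 to 45.3 CPM (-0.49, SE 0.1). The Cd8a call was lost when Th0 replicate 3 or Th17 replicate 2 was left out (-0.52 and -0.54). Which cells account for the falls of Th1 genes was not tested. Gzmb fell from 335 ± 13.7 to 45.6 ± 4.16 CPM (log2 fold change -2.88, SE 0.13) and the Th1 regulator Tbx21 from 54.5 ± 0.32 to 22.8 ± 0.901 CPM (-1.26, SE 0.12), while Ifng measured 4.97 ± 1.45 against 9.72 ± 0.3 CPM (-0.95, SE 0.32, edgeR adjusted p = 0.0525). The Ifng difference passed without Treg replicate 2 or 3 (-0.95 each, edgeR adjusted p = 0.0189 and 0.0158), with RLE scaling (0.0421), with no filter on low counts (0.000186), in a fit of only the 2 groups (0.0357) and without genes of other cell types (0.0487). It also passed with DESeq2 (-1, DESeq2 adjusted p = 0.00927). Of 20 Th1 genes, 9 fell and 5 rose (6 rose and 11 fell adjusted over the list alone; camera adjusted p = 0.0111, and 0.443 with an estimated correlation). That camera call was lost without naive replicate 1 (0.0702), naive replicate 2 (0.0713) or Th17 replicate 3 (0.121). The guanylate binding protein gene Gbp10 (-4.86, SE 0.18), the metallothioneins Mt2 (-3.36, SE 0.29) and Mt1 (-3.13, SE 0.33), the nuclear receptor Nr4a3 (-3.14, SE 0.35) and Rasgef1a (-2.87, SE 0.22) also fell. Iyd, an iodotyrosine deiodinase, had no count in Th0 and was at least 63.9-fold higher, and Ppp1r14c (7.61, SE 0.52), Cd5l (6.61, SE 0.35) and Ccl9 (6.15, SE 0.39) rose. Myeloid markers also rose in these libraries, and which cells made Cd5l and Ccl9 was not tested.

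B lineage genes were higher in the Th17 libraries, where 10 of 12 B cell markers rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 6.34e-08, and 0.201 with an estimated correlation). The B cell factor Pax5 lay at 130 and 135 CPM against 20.6 and 29.3 in Th0 (log2 fold change 2.41, SE 0.34) and Ebf1 at 39.1 and 49.2 against 12.5 and 12.7 (1.81, SE 0.15). The B cell surface gene Ms4a1 measured 14.5 and 12.4 against 10.9 and 19.2 CPM. Of 19 myeloid and dendritic cell markers, 13 rose (15 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0489 with an estimated correlation). Flt3 reached 56.4 and 54.0 CPM from 2.11 and 1.69, and Csf1r reached 2.53 and 3.26 CPM from 0.33 and 0.154. In all, 2362 genes rose and 1849 fell in Th17 against Th0, a total of 4211. It was 2798 without Th0 replicate 3, 2630 without Th17 replicate 2, and 482 when tested against a 2-fold change.

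**Figure D3:**
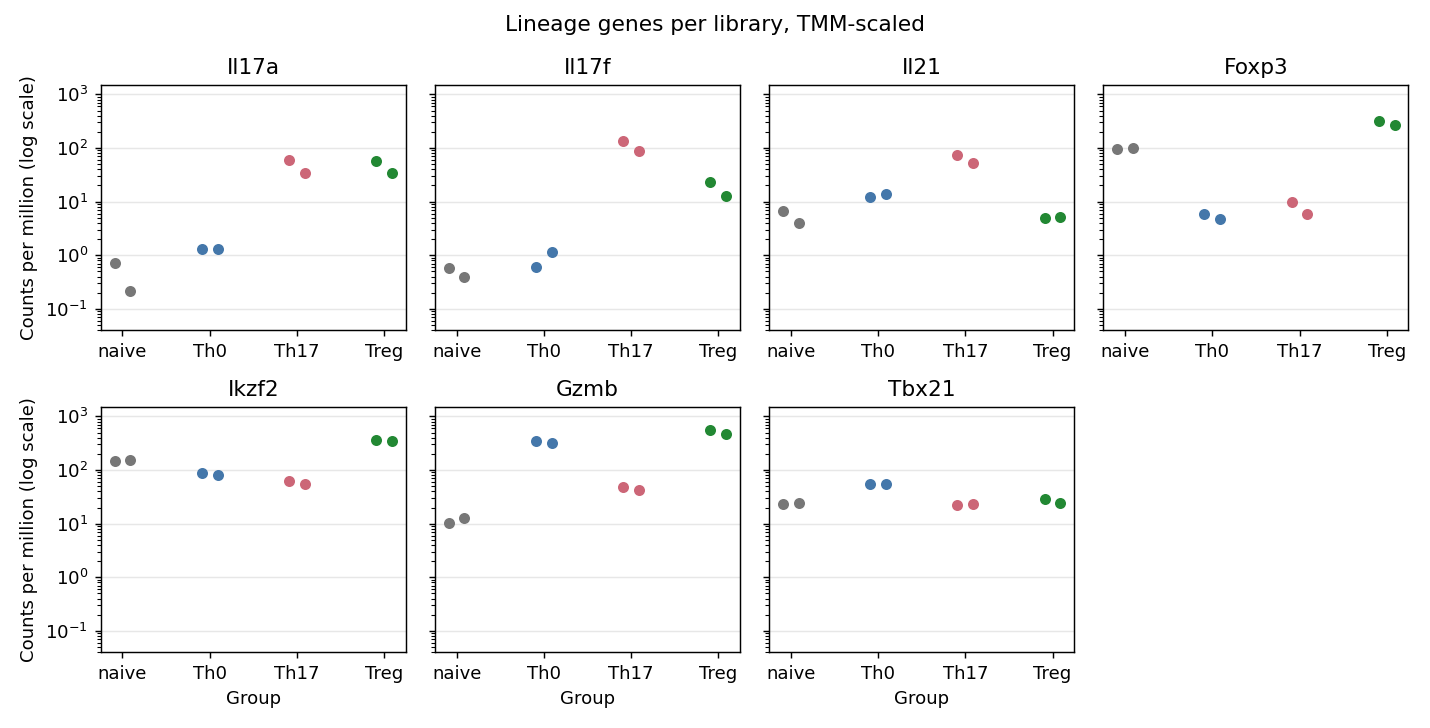
TMM-scaled CPM (log scale) of 7 lineage genes, 1 point per library, 2 libraries per group. Il17a is alike in Th17 and Treg libraries (60.9 and 33.7 against 57.5 and 34.3), whereas Foxp3 is high in Treg (317 and 270) and low in Th17 (9.93 and 5.91).

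Foxp3 and other Treg genes were higher under Treg conditions than in Th0. Foxp3 already lay at 95 and 101 CPM in the naive libraries, above the 5.94 and 4.7 CPM of Th0. Its fold against Th0 is thus not a rise from the naive level, and whether cells newly gained Foxp3 was not tested. Foxp3, on the X chromosome from 7579676 to 7595243, rose from 5.32 ± 0.881 CPM in Th0 to 293 ± 33.5 (log2 fold change 5.78, SE 0.23, edgeR adjusted p = 2.7e-06). Of 22 Treg genes, 17 rose and 1 fell (19 and 2 adjusted over the list alone; camera adjusted p = 1.45e-18, and 0.0486 with an estimated correlation). They included Itgae, an integrin chain of tissue-resident cells (5.19 ± 0.593 to 58.7 ± 3.93 CPM; 3.49, SE 0.15), Nrp1 (3.62, SE 0.28), Ikzf2 (84.0 ± 3.76 to 350 ± 11.9 CPM; 2.06, SE 0.1) and Il2ra (315 ± 11.8 to 1200 ± 56.3 CPM; 1.92, SE 0.12). Of 20 TGF-beta response genes, 12 rose and 2 fell, including Ldlrad4 (2.03, SE 0.17) and Skil (1.83, SE 0.23; camera adjusted p = 0.000155, and 0.112 with an estimated correlation; 13 and 2 adjusted over the list alone).

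Some Th17 and Th1 genes rose in the same libraries. Summed CD8 T cell markers lay at 426 and 469 CPM there against 176 and 176 in Th0, and summed NK cell markers at 69.2 and 59.6 against 13.5 and 12.7. Most of that NK cell sum in Treg came from Klrk1. Of the 7 tested NK cell markers, 3 rose and none fell, and their list did not pass (camera adjusted p = 0.0664). The sum therefore does not show a rise of NK cells. Which cells made the Th1 genes was not tested. Il17a reached 45.9 ± 16.4 CPM (log2 fold change 5.12, SE 0.45, edgeR adjusted p = 6.25e-05) and Il17f 18 CPM (4.39, SE 0.43), and 13 of 20 Th17 genes rose and 2 fell (camera adjusted p = 2.7e-05, and 0.112 with an estimated correlation; the same counts adjusted over the list alone). Ifng rose from 9.72 ± 0.3 to 46.4 ± 20.2 CPM (2.26, SE 0.29), while Tbx21 fell to 26.7 ± 2.79 CPM (-1.03, SE 0.12), in a Th1 list where 12 of 20 rose and 4 fell (camera adjusted p = 0.0111, and 0.462 with an estimated correlation; the same counts adjusted over the list alone). The camera call of that Th1 list was lost without naive replicate 1 (0.0587) or 2 (0.0594). Bcl6, a regulator of follicular helper cells, fell from 94.5 to 21.5 CPM (-2.14, SE 0.2), with 9 of 14 IL-6 and STAT3 response genes falling and 3 rising (camera adjusted p = 0.0111, and 0.201 with an estimated correlation; the same counts adjusted over the list alone). Il2 fell from 3.06 to 0.449 CPM (-2.8, SE 0.75), a call lost without Treg replicate 2 (-1.98, edgeR adjusted p = 0.0894).

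The heat shock genes Hspa1b (266 ± 27.4 to 6.33 ± 0.153 CPM; log2 fold change -5.39, SE 0.69) and Hspa1a (171 ± 8.68 to 4.62 ± 1.71 CPM; -5.22, SE 0.68) fell, as did Hspa1l (-4.9, SE 0.74), Serpinb5 (-8.19, SE 0.44), Notch3 (-3.79, SE 0.27) and Gbp10 (-3.74, SE 0.16). The complement gene Cfb had no count in Th0 and was at least 56.2-fold higher. Arg1, an arginine-degrading enzyme, reached 29.9 ± 2.72 CPM from 1 count in the Th0 libraries, Slc7a2 16.2 ± 1.55 CPM from 2 counts and Sema6d 12.7 ± 4.14 CPM from 2 counts, and Ccl9 (7.51, SE 0.37) and Cd5l (7.5, SE 0.32) rose. Both CD8 T cell markers rose, Cd8a from 112 to 308 CPM (1.46, SE 0.13), and the NK receptor Klrk1 rose from 7.5 to 52.7 CPM (2.82, SE 0.2). Myeloid markers rose in 13 of 19 cases and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0486 with an estimated correlation), and their sum was 154 and 133 CPM in Treg against 70.2 and 63.4 in Th0. Which cells made Cfb, Arg1, Ccl9 and Cd5l was not tested. The counts for Treg against Th0 were 3771 genes higher and 3019 lower, a total of 6790. It was 930 when tested against a 2-fold change.

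Compared directly, Th17 and Treg cells differed in their lineage programs but not detectably in Il17a. Il17a measured 47.3 ± 19.2 CPM in Th17 and 45.9 ± 16.4 in Treg (log2 fold change 0.05, SE 0.32, edgeR adjusted p = 0.939). Il17f was higher in Th17 (112 ± 32.6 against 18 ± 7.1 CPM; 2.64, SE 0.29, edgeR adjusted p = 0.000278), as were Il21 (62.9 against 4.95 CPM; 3.67, SE 0.27) and Socs3 (433 ± 12.3 against 161 ± 3.88 CPM; 1.42, SE 0.1). Of 20 Th17 genes, 13 were higher in Th17 and 1 lower, and of 14 IL-6 and STAT3 response genes 11 were higher and 1 lower (12 and 1 adjusted over the list alone). Of 22 Treg genes, 15 were lower in Th17 and 2 higher (18 and 2 adjusted over the list alone), led by Foxp3 (-5.19, SE 0.22), Nrp1 (-2.7, SE 0.25) and Ikzf2 (-2.57, SE 0.1). These 3 lists also passed with an estimated correlation (camera adjusted p = 0.0486 for each). Il2ra (-0.71, SE 0.12) and Itgae (-1.92, SE 0.13) were lower in Th17. Il23r was higher (1.93, SE 0.51), a call lost without Th17 replicate 2 (1.18, edgeR adjusted p = 0.175), Treg replicate 2 (1.62, 0.149) or Treg replicate 3 (2.29, 0.056).

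Gzmb, Eomes, Ifng and other genes of the Th1 list were lower in Th17 than in Treg. Gzmb measured 45.6 against 510 CPM (log2 fold change -3.48, SE 0.14), Eomes 0.878 against 16.0 (-4.16, SE 0.25) and Ifng 4.97 against 46.4 (-3.21, SE 0.31), with 10 of 20 Th1 genes lower and 2 higher (3 higher and 11 lower adjusted over the list alone; camera adjusted p = 8.62e-09, and 0.152 with an estimated correlation). Cd8a lay at 76.8 against 308 CPM in the same libraries (-2, SE 0.14) and Klrk1 at 6.34 against 52.7 (-3.05, SE 0.2). Follicular helper genes were higher in Th17 in 7 of 11 cases and lower in 2, including Cxcr5 (1.66, SE 0.16; camera adjusted p = 9.22e-05, and 0.107 with an estimated correlation; 7 and 3 adjusted over the list alone). Of 26 proliferation genes, 13 were lower in Th17 and 3 higher, among them Ccne2 (-1.67, SE 0.23) and Pcna (-1.05, SE 0.13; camera adjusted p = 0.000676, and 0.398 with an estimated correlation; 3 higher and 14 lower adjusted over the list alone). Oxidative phosphorylation genes were lower in 12 of 24 cases and higher in none (0 and 13 adjusted over the list alone; camera adjusted p = 0.00167, and 0.337 with an estimated correlation).

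Among the greatest differences, Serpinb5 (6.99, SE 0.45), Gramd2 (6.18, SE 0.52), Cox6a2 (5.41, SE 0.58), the phosphatase Alpl (5.08, SE 0.23), Sox5 (5.07, SE 0.58) and Iyd (13.7 ± 1.84 CPM against 3 counts in total) were higher in Th17. Ifit1bl1 (-5.65, SE 0.4), Ptrf (-4.87, SE 0.42), the interferon-induced GTPase Iigp1 (-4.78, SE 0.48) and Lcn10 (-4.25, SE 0.42) were lower. B cell markers were higher in Th17 in 10 of 12 cases and lower in 1, with Pax5 at 133 against 13.3 CPM (7.01 and 19.6 in the Treg libraries; 3.34, SE 0.37; camera adjusted p = 2.9e-13, and 0.14 with an estimated correlation; the same counts adjusted over the list alone). In all, 2169 genes were higher and 2125 lower, a total of 4294. It was 2444 without Th17 replicate 3, 1878 without Treg replicate 2, and 456 when tested against a 2-fold change.

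Phospholipid synthesis and remodeling genes, the theme of the series title, did not pass camera as a group in any contrast when all libraries were used with the filter on low counts. Of 60 tested, 15 rose and 20 fell in Th0 against naive, 15 rose and 3 fell in Th17 against Th0, 19 rose and 14 fell in Treg against Th0, and 10 were higher and 3 lower in Th17 against Treg (camera adjusted p = 0.346, 0.0654, 0.641 and 0.245). Adjusted over the list alone, the counts were 15 and 20, 16 and 3, 20 and 14, and 10 and 3. The Th17 against Th0 test passed without Th17 replicate 2 (camera adjusted p = 0.033), Treg replicate 2 (0.0391) or Treg replicate 3 (0.0433), and with no filter on low counts (0.0234). With fry, which asks a different question of the list alone, the adjusted p was 0.000667, 0.00101, 0.00562 and 0.00763 in the same contrast order. Its direction was down in Th0 against naive and up in the other contrasts. Fry passed 78 of all 112 list tests, so these values do not set this list apart. Enpp2, which makes lysophosphatidic acid, measured 39.1 CPM in Th17, 10.3 in Th0 and 5.98 in Treg. It was higher in Th17 than in Th0 (log2 fold change 1.92, SE 0.25) and than in Treg (2.72, SE 0.26, edgeR adjusted p = 0.000143). The acyltransferase gene Mboat1 was higher in Treg than in Th17 (23.5 against 8.3 CPM; -1.49, SE 0.22). The phospholipase genes Pla2g7 and Pla2g4a fell in Th0 against naive (59.1 to 0.215 and 21.3 to 0.132 CPM), as did the acyltransferase gene Lpcat2 (42.4 to 0.605 CPM), alongside the myeloid markers, which summed to 4390 and 4150 CPM in naive and 70.2 and 63.4 in Th0. Pla2g7 rose to 5.9 CPM in Th17 and 4.41 in Treg, where that sum was 165 and 179, and 154 and 133.

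**Figure D4:**
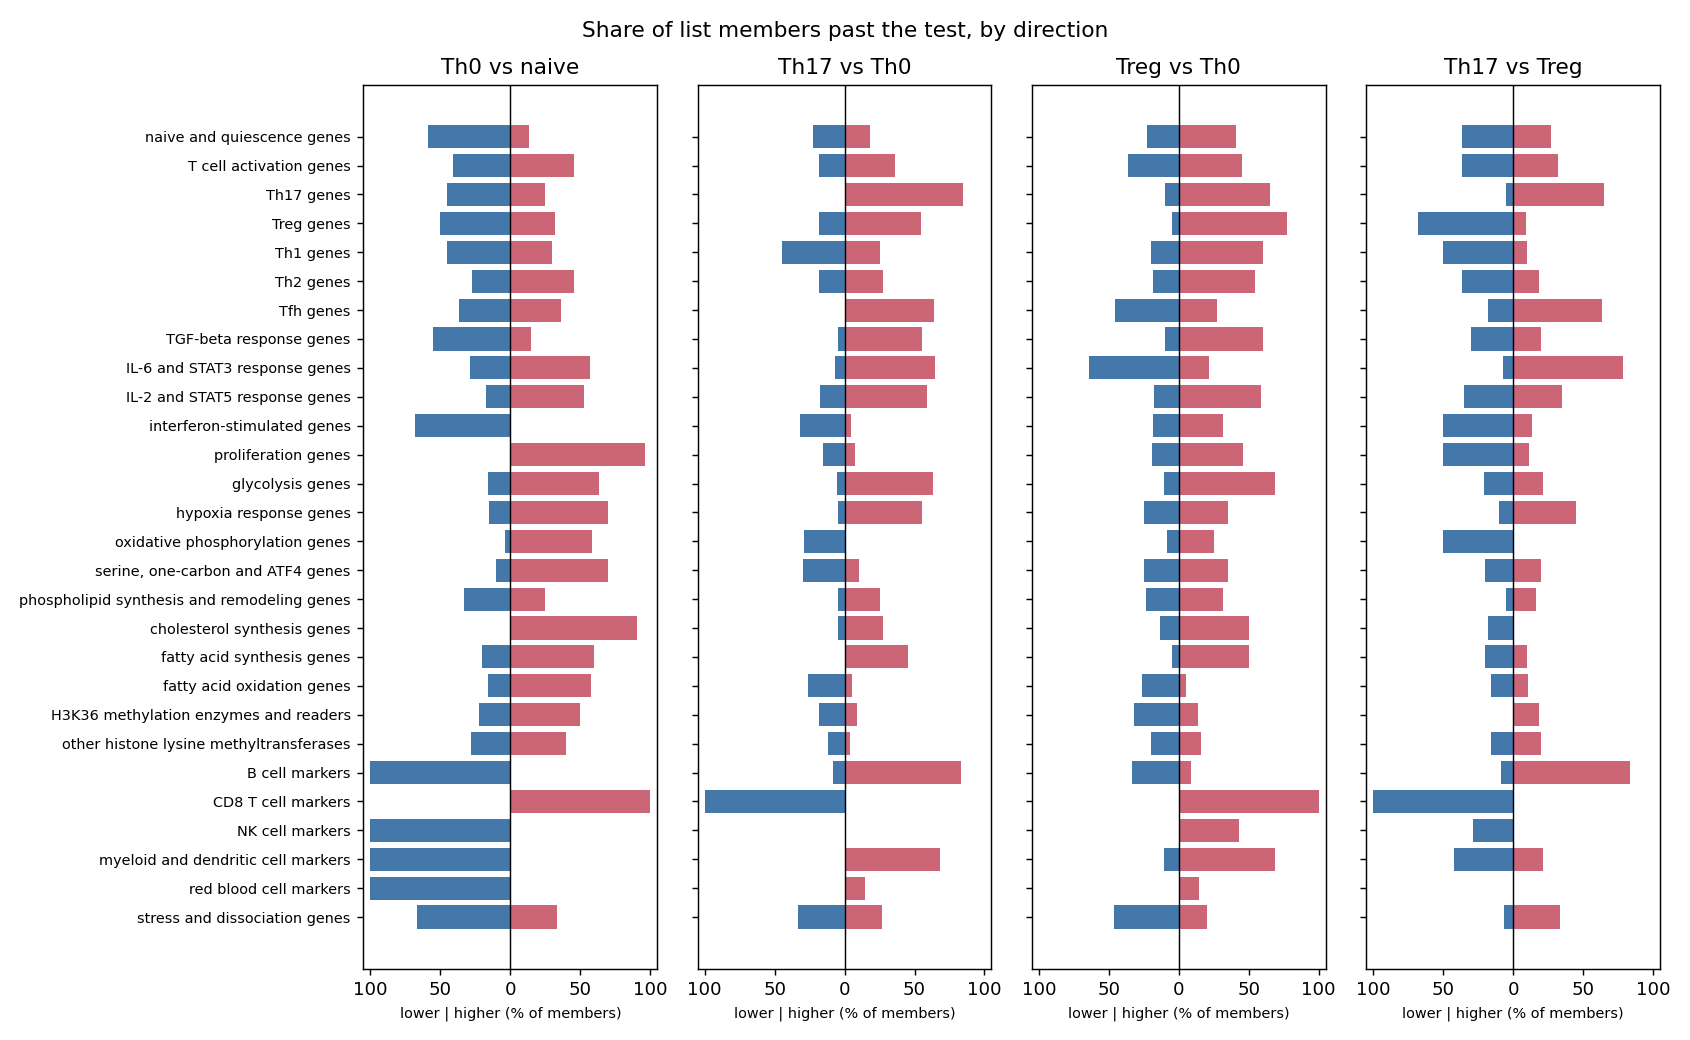
Percent of the tested members of each of the 28 gene lists that passed the edgeR test as higher (right, red) or lower (left, blue) in 4 contrasts, with 2 libraries per group. The Th17 list rises in 17 of 20 members in Th17 against Th0, and the Treg list in 17 of 22 in Treg against Th0.

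Many genes moved the same way under both differentiation conditions. Against Th0, 1557 genes were higher and 1280 lower in both Th17 and Treg, where independent lists of these sizes would share 606 and 380. Which direction held more genes depended on the scaling and the test, with 1415 higher and 1498 lower under RLE scaling, 1254 and 1412 with DESeq2, and 1395 and 1399 with limma-voom. Among them were Hk2 (log2 fold change 3.25 and 2.71), Cd5l (6.61 and 7.5), Ccl9 (6.15 and 7.51) and Setd2 (-0.48 and -0.71). Myeloid and dendritic cell markers also rose in both, 13 of 19 in each, as did 72.0% and 76.0% of 25 further macrophage and monocyte genes, a list chosen after seeing the data. Which cells made Cd5l and Ccl9 was not tested, so their rises cannot be credited to T cells. Another 234 genes moved in opposite directions, where independent lists would share 959. Of those, 150 were higher in Th17 and lower in Treg, such as Il21 (2.27 and -1.39), and 84 were lower in Th17 and higher in Treg, such as Gzmb (-2.88 and 0.61) and Eomes (-2.34 and 1.82). Both contrasts use the same Th0 libraries: 20 simulations of unchanged groups gave a mean of 0.1 shared higher and 0.15 shared lower genes (at most 1 of each). They called a mean of only 0.6 genes higher and 0.55 lower in Th17, and 0.7 and 0.75 in Treg, so hardly any could be shared. These overlaps cannot show what the shared libraries add when many genes change. The fold changes correlated at 0.66 across genes against a simulated mean of 0.508, with a covariance of 1.138 against 0.111, a difference of 1.027. Part of the excess may come from the shared libraries, which are too few to split. The 2837 shared genes were 1844 without Th0 replicate 3, 1706 without Th17 replicate 2, and 236 when tested against a 2-fold change.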

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

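No call of a gene named by the rule or of a list reversed its direction in any of the alternatives run, but the split of calls between higher and lower did not hold in all of them. Fits without the naive libraries and without marker genes of other cell types were chosen after seeing the data. Tested against a 2-fold change, the counts of genes fell to 4231 (Th0 against naive), 482 (Th17 against Th0), 930 (Treg against Th0), 456 (Th17 against Treg) and 236 (shared by Th17 and Treg against Th0), and Setd2 lost its calls in Th17 against Th0 and against naive (-0.48 each) and in Treg against Th0 and against naive (-0.71 each). That test asks for more than any change by its construction. With the correlation estimated per list, 9 of 112 list tests passed in place of 54. With 1 library left out, the counts ranged from 8585 to 10375, from 2630 to 4190, from 4637 to 7081, from 1878 to 4338 and, for shared genes, from 1706 to 3125, and 45 to 57 list tests passed. Setd2 then ranged from -0.6 to -0.36 in Th17 against Th0, from -0.86 to -0.64 in Treg against Th0, from 0.11 to 0.35 in Th17 against Treg, from -0.1 to 0.12 in Th0 against naive, from -0.6 to -0.36 in Th17 against naive and from -0.76 to -0.66 in Treg against naive. Fits without the naive libraries called 3703, 6272 and 3680 genes (Th17 against Th0, Treg against Th0, Th17 against Treg). Fits without marker genes of other cell types called 9867, 4153, 6742 and 4152, but they kept all other transcripts of such cells and so cannot test their contribution. DESeq2 called 1950 genes higher and 1966 lower in Th17 against Th0, in place of 2362 and 1849, and RLE scaling moved the share of higher calls from 56.1% to 50.7% in Th17 against Th0 and from 55.5% to 50.3% in Treg against Th0. Of 461 gene results named by the rule, Setd2 not counted, 185 lost their call against a 2-fold change and 73 in at least 1 other alternative, and 2 gained one. In the simulations, with 100 genes changed 2-fold and 100 changed 4-fold per contrast, 55% to 69% of the 2-fold changes were called. Far more genes were called in these data, which makes the adjusted threshold less strict, so the share found here may be higher and is not known. A missing call does not show that a gene was unchanged.

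The replicate block (replicate number as a term) called 9200, 3101, 5599 and 4165 genes in the same order, 2046 shared genes and 44 list tests. It left Setd2 at -0.46 in Th17 against Th0 (edgeR adjusted p = 0.025) and -0.69 in Treg against Th0 (0.00224), and Ifng passed in Th17 against Th0 (-1.2, 0.0086). The block terms leave fewer residual degrees of freedom than the 4 of the main fit, so calls can be lost through lower power alone. With the block, 10 list calls were lost. Among them were Th1 genes in Th17 against Th0 (camera adjusted p = 0.0911) and in Treg against Th0 (0.0503), and follicular helper genes in Th17 against Treg (0.0503). No label says that the numbers pair the samples, and deviations of same-numbered libraries from their group means correlated at 0.14 in Th17 and Treg, 0.17 in Th0 and Th17, 0.06 in naive and Th17, -0.02 in naive and Th0, and 0 in the other pairs. The deviations of the 2 libraries of a group mirror each other, so differently numbered pairs gave the same values apart from sign. Th0 replicate 1 and Th17 replicate 2, for example, also correlated at 0.17. These correlations therefore cannot show whether the numbers pair the samples.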

Other observations

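Mitochondrial transcripts did not move as 1 group. The gene mt-Co1 took 1.44% and 1.47% of counts in the naive libraries, 2.51% and 2.29% in Th0, 1.97% and 2.21% in Th17 and 1.38% and 1.55% in Treg. All other mitochondrial genes together took 2.75% and 2.87% in naive, 1.14% and 0.9% in Th0, 1.41% and 1.45% in Th17 and 1.49% and 1.44% in Treg. The complex I gene mt-Nd4 lay at 3040 and 3050 CPM in naive, 514 and 382 in Th0, 898 and 624 in Th17 and 1350 and 1230 in Treg, whereas mt-Co3 lay at 3630 and 3650, 3430 and 2920, 2900 and 2860, and 2600 and 2560. Pan T cell genes, a list of 18 chosen after seeing the data, had 9 higher and 3 lower in Th0 against naive, 1 higher and 9 lower in Th17 against Th0, 5 higher and 7 lower in Treg against Th0, and none higher and 10 lower in Th17 against Treg. Ccl20, a Th17 chemokine gene too low to be tested, had 8 and 14 counts in the Treg libraries and 0 in the other 6.

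The patterns weighed here were noticed in the data. Chosen only after the result was seen were the red blood cell test and the 3 tests of single libraries (naive, Th17 and Th0). The tests of further macrophage, further B cell, early lymphoid and heat shock factor genes had their bounds set before those lists were looked at.

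Myeloid markers fell in Th0 against naive, and a single naive library does not account for it, since both naive libraries lay above every cultured library for 19 of 19 markers. Cells of other types in the naive libraries are a candidate explanation: 96.0% of the 25 tested genes of a further macrophage and monocyte list, none of them in the fixed lists, were at least 4-fold lower in Th0. That list would also fall if T cells themselves lost such transcripts, so it cannot tell the explanations apart. Csf1r stood at 862 and 820 CPM and Mpeg1 at 963 and 934 CPM in naive, although the labels describe selected CD4+ cells. Loss of these transcripts from the T cells themselves on activation stays open: the median log2 fold change of the 7 red blood cell markers was -8.42 (-7.84 with genes at 0 counts set at their bound, SD 1.76), which shows that genes T cells are not known to make moved too but not where the myeloid transcripts came from. The bound first set for that test, which would have excluded this explanation on the red blood cell value, was therefore wrong by its own logic and was not used.

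B lineage genes rose in Th17, and a single library does not account for it, because at least 10 B cell markers passed as higher without either Th17 library. B cells in these libraries may contribute: the median log2 fold change of 22 further B cell genes, none in the fixed lists, was 1.04 against a bound of 1 set beforehand, a narrow pass with quartiles of 0.57 and 1.67. The rise differed between genes, from 64.9% of the naive level for Ebf1 and 54.8% for Pax5 to 10.5% for Ighm, 7.25% for Cd74, 3.57% for Igkc and -0.659% for Ms4a1. Fcer2a (-10.5%) was lower in Th17 than in Th0. Vpreb3 (-2.92%) and Ralgps2 (-7.4%) had lower means but did not pass the test (edgeR adjusted p = 0.711 and 0.242). The rise did not follow the naive level alone. Early lymphoid cells cannot be told apart from the alternatives, since 44.4% of 9 tested genes rose where the bounds were 50% and 25%. That list held Il7r, whose value had been seen, and without it 4 of 8 rose, at the upper bound. Those 4 were Cd93, Mef2c, Bcl11a and Pou2af1, whereas Dntt did not differ (log2 fold change -0.12, SE 0.29, edgeR adjusted p = 0.799) and Rag1 was at 0 CPM in Th0 and Th17. All 9 tested genes of that list were lower in Th0 than in naive, as the B cell markers were. Rises in the list may thus also come from B cells, and their share cannot separate the cell types. A change within T cells under Th17 conditions was not tested and stays open.

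Hspa1a and Hspa1b were high in Th0, and a single library does not account for it, since for both genes (2 of 2) both Th0 libraries lay above every Th17 and Treg library. Whether a heat shock factor response in the Th0 libraries, from handling or culture, could be the cause was not decided: 47.1% of 17 heat shock factor genes were lower in Treg than in Th0 and 17.6% were higher, between bounds of 50% and 25%, while 70.6% were higher and 11.8% lower in Th0 than in naive, and 35.3% were lower and none higher in Th17 than in Th0, contrasts for which no bound was set. Hsph1, Dnaja1 and Hspe1 fell from 256.6, 278.2 and 383.1 CPM in Th0 to 70.92, 103.4 and 133.2 in Treg, whereas Hspd1 measured 311 and 361.8. The 2 Th17 libraries also stood apart, with Hspa1b at 32.2 and 132 CPM. An effect of the culture conditions on these genes is the biological alternative and was not tested.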
